A study of Mus musculus with 21 samples.

How the data were processed

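Fractionation iCLIP was carried out in P19 cells, a mouse embryonal carcinoma line, expressing SRSF3-GFP or SRSF7-GFP. SRSF3 and SRSF7 are SR proteins, RNA-binding proteins with a serine/arginine-rich domain that act in splicing and in later steps of mRNA metabolism. In iCLIP, ultraviolet light links a protein to the RNA it touches, the protein is purified, and reverse transcription stops at the linked nucleotide, so the start of each cDNA marks a bound position. Cells were irradiated at 254 nm with 100 mJ/cm2 and fractionated into chromatin, nucleoplasm and cytoplasm before iCLIP, per the labels' protocols. The labels describe 21 samples in 6 groups, with 4 replicates per fraction for SRSF3 and 3 for SRSF7. Each adapter carries random nucleotides around a fixed barcode, per the labels, which allows copies of 1 cDNA to be recognised. How duplicates were removed, and the aligner and peak caller with their versions, are not given in the sources used here.

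The authors pooled the replicates of each group and deposited 1 list of positions per group, per the sample descriptions in the labels. Each deposited entry is 1 nucleotide wide and holds a whole number of either sign, the cDNA count at that position. The sign was read as the strand, which is an inference from the values and the file layout. The authors listed positions that passed a false discovery rate below 0.05 against 100 permutations with a 15 nt neighbourhood, with regions treated separately, per the file headers. The 3 SRSF7 track names also carry a term for regions treated as one, while their descriptions say separately, so a difference in peak calling between the proteins is not excluded. Coordinates are of build mm9, per the submitters' processing notes and the file headers, and are given 1-based. The counts were not scaled to depth by the authors as far as the values show.

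The values are therefore counts in peaks, not in whole libraries. The samples include none without a tagged protein, so background cDNAs could not be told from bound ones. A weakly bound position passes the threshold more easily in a deeper file, and a locus missing from a list is not shown to be unbound. The listed total ranged from 248498 cDNAs in SRSF7 chromatin to 1768665 in SRSF3 chromatin. Each group is 1 pooled value, so no spread between replicates could be measured and no p-value is given. Shares carry exact 95% Clopper-Pearson intervals and ratios of shares carry 95% conditional exact binomial intervals. These cover counting error only and are too narrow wherever replicates or fractionations vary.

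Shared positions were counted when a position of one file lay within 5 nt of a position of another file on the same strand. The comparison value came from moving each position of the first file by a random 100 to 500 nt in either direction, in 100 draws. A move of that size carries positions of the shortest loci off the locus, so the moved value does not hold the bound RNA fixed there. Clusters joined positions of the 3 files of a protein at gaps of up to 30 nt on 1 strand. Loci joined positions of all 6 files at gaps of up to 10000 nt on 1 strand, which can merge neighbouring genes or split a long one. A locus entered a comparison with at least 50 cDNAs in both files together and at least 10 in each. It was counted as higher or lower when its interval lay beyond 2-fold. Loci named in the text are the 5 with the highest share in each file and, for chromatin against cytoplasm and for SRSF3 against SRSF7, those with the highest and lowest ratios among loci beyond 2-fold. That rule takes 8 in each direction, of which the first 2 are printed. The rule, the comparisons and most alternatives were fixed before the data were examined. Loci named outside the rule are said to be so.

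The comparison of loci was tested on simulated data. Counts were drawn for the real loci at the mean share of the 2 files, with 200 loci changed by known folds. Changed loci were taken only from those expected, before the change, to hold well over 10 cDNAs in the smaller file. Recovery of loci near the minimum was therefore not tested. Of loci changed 4-fold, 95.5% were recovered in SRSF7 nucleoplasm against cytoplasm, where 1393 loci were compared, and 100% in SRSF3 chromatin against cytoplasm, where 2537 were compared. The real files gave fewer loci to compare, 1248 and 1050 for these 2 pairs. Calls among unchanged loci numbered 0 in both, under counting error alone. Unchanged loci had equal shares, so a call there needed counting error to carry the whole interval beyond 2-fold. Alternatives were positions with at least 3 cDNAs, files thinned at random to 248498 cDNAs, other distances and gaps, at least 200 cDNAs per locus, numbers of positions in place of cDNAs, and shares without the mitochondrial genome and the 10 highest loci. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

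No annotation or genome of build mm9 was used here, and the gene table at hand is of another assembly. Positions were therefore not assigned to genes, introns, exons or untranslated regions. Shares per region, introns bound in all fractions, gene lists, sequence at sites and distance to splice sites were planned and not analysed here, and neither were the SRSF3 and SRSF7 genes themselves. The design asks about persistent binding to retained introns. That question was addressed at the level of positions and loci only.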

Results

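Binding of SRSF3-GFP and SRSF7-GFP was mapped in chromatin, nucleoplasm and cytoplasm of P19 cells, with 1 pooled list of positions per protein and fraction. The SRSF3 lists held 870234 positions with 1768665 cDNAs in chromatin, 109400 positions with 315510 cDNAs in nucleoplasm and 58686 positions with 257089 cDNAs in cytoplasm. The SRSF7 lists held 76172 positions with 248498 cDNAs in chromatin, 130679 with 275018 in nucleoplasm and 142444 with 367298 in cytoplasm. SRSF3 was thus listed most widely in chromatin, and SRSF7 in cytoplasm. Mean counts per position ran from 2.03 in SRSF3 chromatin to 4.38 in SRSF3 cytoplasm, and between 61.1% and 71.8% of positions carried a single cDNA. There was no replicate spread to set any difference against, because replicates were pooled before deposit.

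Mitochondrial RNA took a far larger share of both proteins' cDNAs in cytoplasm than in chromatin. In SRSF3 it made up 0.196% of chromatin cDNAs (95% interval 0.190 to 0.203), 9.79% in nucleoplasm (9.69 to 9.90) and 16.7% in cytoplasm (16.6 to 16.8). In SRSF7 the shares were 0.322% (0.30 to 0.345), 1.44% (1.40 to 1.49) and 8.89% (8.79 to 8.98). The share in cytoplasm was 85.1-fold that in chromatin for SRSF3 (82.2 to 88.1) and 27.6-fold for SRSF7 (25.8 to 29.7). With positions of at least 3 cDNAs, an alternative chosen after seeing the data, the shares in chromatin and cytoplasm were 0.368% and 20.6% for SRSF3 and 0.328% and 14.5% for SRSF7. The folds were then 56.0 (54.0 to 58.0) and 44.4 (40.8 to 48.3), much closer to each other. The proteins differed most in nucleoplasm, where the SRSF3 share was 6.79-fold the SRSF7 share (6.57 to 7.02). In that fraction 1952 mitochondrial positions with a mean of 15.8 cDNAs were listed for SRSF3, against 439 positions with a mean of 9.03 for SRSF7. Intervals are exact and cover counting error only, and that alternative gave 14.5% for SRSF3 nucleoplasm and 2.69% for SRSF7 nucleoplasm.

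A single locus held the largest share in all 6 files. It lies on chromosome 17 at 39979938 to 39985047 of mm9, on the plus strand. SRSF3 had 9.38% of its chromatin cDNAs there (9.34 to 9.42), 16.7% in nucleoplasm (16.5 to 16.8) and 21.9% in cytoplasm (21.7 to 22.0). For SRSF7 the values were 19.7% (19.6 to 19.9), 6.11% (6.02 to 6.20) and 17.3% (17.2 to 17.4). Nucleoplasm thus lay above chromatin in SRSF3 and below it in SRSF7. The locus carried between 1793 and 3007 listed positions per file.

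**Figure D1:**
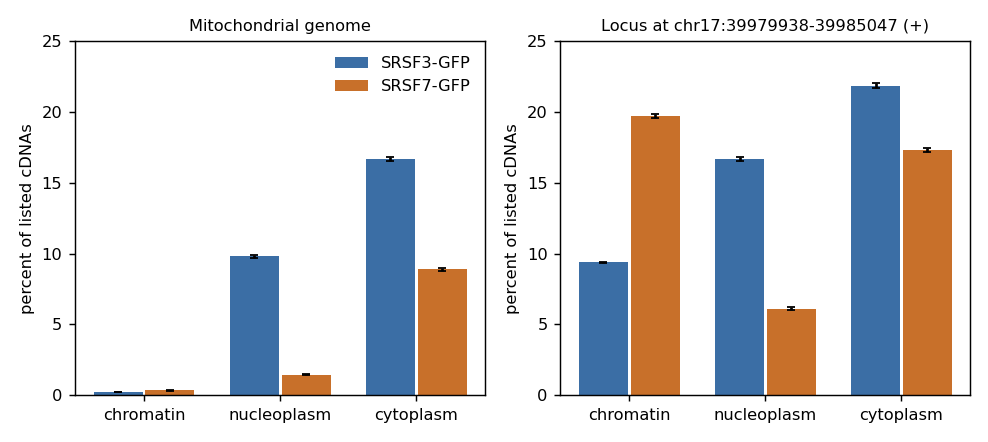
Percent of listed cDNAs in the mitochondrial genome (left) and in the locus with the highest share (right), on the vertical axes, for each fraction and protein. Bars are the 6 pooled files and error bars are exact 95% intervals for counting error; the SRSF3 nucleoplasm bar stands at 9.79% on the left, against 1.44% for SRSF7.

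The other leading loci differed in which fraction they belonged to. A locus on the minus strand of chromosome 19 at 5794731 to 5803434 held 1.94% of SRSF3 cDNAs in chromatin, 1.02% in nucleoplasm and 0.698% in cytoplasm. In SRSF7 it held 4.05%, 3.82% and 1.67%. A short locus of 454 nt on the minus strand of chromosome 11 at 108872978 to 108873431 held more of both proteins' cytoplasm than of their chromatin, with 2.36% against 0.901% in SRSF3 and 2.63% against 1.64% in SRSF7. A locus of 126 nt on the minus strand of chromosome 9 at 78023133 to 78023258 held 2.07% of SRSF3 nucleoplasm, 1.89% of SRSF3 cytoplasm and 0.163% of SRSF3 chromatin. A locus on the minus strand of chromosome 7 at 118211535 to 118226516 stood out in SRSF3 nucleoplasm at 2.23%, against 0.130% in chromatin and 0.248% in cytoplasm. In SRSF7 nucleoplasm it held 0.457%. The plus strand of chromosome 1 at 11056686 to 11244752, a long locus, ranked 4th in SRSF3 chromatin with 1.20%. The minus strand of chromosome 13 at 28679218 to 28989636, also long, ranked 5th there with 1.20%. In SRSF3 cytoplasm these held 0.00467% and 0.0229%.
The minus strand of chromosome 7 at 67105899 to 67150421 was more even, with between 0.725% and 2.16% in the 6 files. A locus on the plus strand of chromosome 1 at 162965305 to 162970711 held 1.5% of SRSF7 nucleoplasm, 0.741% of SRSF7 chromatin and 0.0607% of SRSF7 cytoplasm. The 10 highest loci together took 18.7% of cDNAs in SRSF3 chromatin, the lowest of the 6 files, and 49.4% in SRSF3 cytoplasm, the highest.

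The first question of the design is whether the same positions are bound in the 3 fractions. For SRSF3, 55.4% of cytoplasmic positions (55.0 to 55.8) lay within 5 nt of a chromatin position on the same strand. The value was 57.7% for nucleoplasm against chromatin and 59.7% for cytoplasm against nucleoplasm. For SRSF7 the corresponding shares were 19.8% (19.6 to 20.1), 26.7% and 32.8%. Moving the positions by 100 to 500 nt left 10.9%, 14.7% and 9.21% for SRSF3, and 5.08%, 6.89% and 8.60% for SRSF7. Observed sharing was therefore between 3.81-fold and 6.48-fold the moved value in these 6 pairs. These folds do not separate shared nucleotides from shared short loci, because the move can leave a short locus. Loci under 1 kb held 18736 of the 58686 SRSF3 cytoplasmic positions and 18364 of the 142444 SRSF7 ones. In the same order, the folds were 5.095, 3.92 and 6.48 for SRSF3 and 3.91, 3.87 and 3.81 for SRSF7. SRSF7 positions near SRSF3 positions of the same fraction reached 3.33-fold in chromatin, 4.43-fold in nucleoplasm and 4.999-fold in cytoplasm. Sharing above the moved value also arose between different proteins, so it does not by itself show that 1 protein stays bound across fractions. Tall positions were shared most. Of SRSF7 cytoplasmic positions with 6 or more cDNAs 78.4% had a chromatin partner, against 13.3% of those with 1 cDNA, and the SRSF3 values were 79.6% and 49.0%. No moved value was computed by height, so sharing beyond the moved value was not compared between heights. With positions of at least 3 cDNAs, the moved values for cytoplasm against chromatin rose to 13.3% in SRSF3 and 13.8% in SRSF7.

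**Figure D2:**
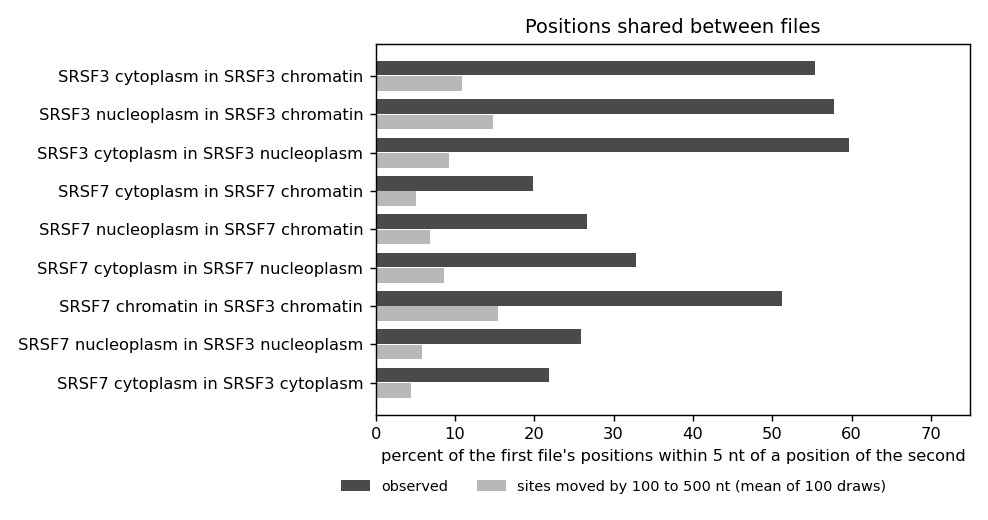
Percent of the positions of the first file that lie within 5 nt of a position of the second, on the horizontal axis, for 9 pairs of files. Dark bars are observed values and light bars the mean after moving the first file's positions; in SRSF3 cytoplasm against chromatin they stand at 55.4% and 10.9%.

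These shares depend on how many positions the second file lists, and the SRSF3 chromatin file is the longest. With all files thinned to 248498 cDNAs, SRSF3 cytoplasm shared 39.2% with chromatin (moved value 7.78%) against 21.8% for SRSF7 (5.64%). With positions of at least 3 cDNAs the values were 64.3% and 48.5%. Neither setting removes the dependence. Thinning equalises cDNAs, not positions, and the filter left 103615 chromatin positions in SRSF3 against 14157 in SRSF7.

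Clusters present in all 3 fractions numbered 3434 of 164448 for SRSF3 and 3151 of 68765 for SRSF7. They made up 29.8% of cytoplasmic SRSF3 clusters and 9.61% of cytoplasmic SRSF7 clusters. Moving the nucleoplasm and cytoplasm positions gave a mean of 1480 for SRSF3 and 1446 for SRSF7 over 20 draws. Observed numbers were thus 2.32-fold and 2.18-fold the moved ones, with the same limit for short loci. Independent lists over the clusters listed in at least 1 of the 3 files would give 1256 for SRSF3 and 4218 for SRSF7. That value leaves out clusters in no file, so it cannot show whether sharing lay above or below independence. When all 6 files were joined, 1306 clusters were present in all 3 fractions of both proteins. No moved value was computed for this number. These were 38% of the SRSF3 clusters of that kind and 41.9% of those of SRSF7. With positions of at least 3 cDNAs, clusters in all 3 fractions numbered 1321 for SRSF3 and 813 for SRSF7.

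Within SRSF3, chromatin and cytoplasm differed widely in which loci held their cDNAs. Of 1050 loci compared, 218 held a share beyond 2-fold higher in chromatin and 399 beyond 2-fold higher in cytoplasm. Chromatin-higher loci were long, with a median span of 37.9 kb, and cytoplasm-higher loci short, with a median of 1.29 kb. The highest ratio belonged to the long locus on the plus strand of chromosome 1 at 11056686 to 11244752, with 21236 cDNAs over 12308 positions in chromatin and 12 over 10 positions in cytoplasm, a log2 ratio of 8.01 (7.20 to 8.96). Next came the minus strand of chromosome 8 at 49515773 to 49641270, with 4674 and 10 cDNAs and a log2 ratio of 6.09 (5.21 to 7.15). At the other end stood 5 nt on the minus strand of chromosome 7 at 111785248 to 111785252, with 13 cDNAs in chromatin and 415 in cytoplasm, a log2 ratio of -7.78 (-8.70 to -6.99). It was followed by 18 nt on the minus strand of chromosome 9 at 66378138 to 66378155, at -6.69 (-7.67 to -5.85). A further 1676 loci had at least 50 cDNAs in chromatin and were not listed in cytoplasm, and 6 had the reverse.
The balance of directions turned with at least 200 cDNAs per locus, to 218 chromatin-higher and 143 cytoplasm-higher, and after thinning, to 197 and 163. Of the loci beyond 2-fold, the filter at 200 cDNAs removed only cytoplasm-higher ones, because the chromatin file is far the larger. That turn follows from the filter and says nothing about binding. The ratio of the median spans was 29.4, against 9.64 after thinning, 40.2 with positions of at least 3 cDNAs and 30.55 with loci joined at 1000 nt (3 alternatives chosen after seeing the data). Loci were joined over all 6 files, and spans were not measured without the positions of SRSF3 chromatin.

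Within SRSF7, 190 of 852 loci held a share beyond 2-fold higher in chromatin and 143 beyond 2-fold higher in cytoplasm. A further 18 loci had at least 50 cDNAs in chromatin and were not listed in cytoplasm, and 127 had the reverse. The split of compared loci therefore leaves out more cytoplasm loci than chromatin loci. Chromatin-higher loci had a median span of 12.0 kb and cytoplasm-higher loci 19.8 kb. The highest ratio was at 170 nt on the minus strand of chromosome 12 at 103491728 to 103491897, with 318 cDNAs over 45 positions in chromatin and 10 over 6 in cytoplasm, a log2 ratio of 5.55 (4.66 to 6.63). The minus strand of chromosome 14 at 31825550 to 31832202 followed at 5.03 (4.44 to 5.68). The lowest ratios were on the plus strand of chromosome 10 at 56096419 to 56111527, with 14 and 1069 cDNAs and a log2 ratio of -5.69 (-6.57 to -4.94), and on the plus strand of chromosome 19 at 44368569 to 44383355, with 25 and 1901 cDNAs and -5.68 (-6.32 to -5.12). Both also held a larger share of SRSF3 cytoplasm than of SRSF3 chromatin. The order of the median spans turned with positions of at least 3 cDNAs, where the chromatin-higher median was 17.8 times the cytoplasm-higher one, and with loci joined at 1000 nt, where it was 2.64 times (2 alternatives chosen after seeing the data).

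Nucleoplasm was also set against each of the other fractions. In SRSF3, 305 loci were beyond 2-fold higher in chromatin than in nucleoplasm and 562 lower, of 1778, while 155 were higher in nucleoplasm than in cytoplasm and 77 lower, of 921. In SRSF7, 130 were higher in chromatin than in nucleoplasm and 197 lower, of 915, and 282 were higher in nucleoplasm than in cytoplasm and 207 lower, of 1248. Loci with at least 50 cDNAs in 1 fraction and none listed in the other were not compared. Only in chromatin and only in nucleoplasm, they numbered 1066 and 3 in SRSF3 and 9 and 17 in SRSF7. Only in nucleoplasm and only in cytoplasm, they numbered 41 and 7 in SRSF3 and 8 and 38 in SRSF7. In SRSF3, the median span was 54.3 kb for loci higher in chromatin than in nucleoplasm and 3.58 kb for those lower, and 14.8 kb for loci higher in nucleoplasm than in cytoplasm and 0.408 kb for those lower. In SRSF7, the first pair ran the other way, with 2.41 kb and 25.4 kb, and the second gave 21.8 kb and 13.8 kb. Without the mitochondrial genome and the 10 highest loci, the split between nucleoplasm and cytoplasm turned to 101 higher and 123 lower in SRSF3 and to 208 and 246 in SRSF7. Chromatin against nucleoplasm turned to 305 higher and 147 lower in SRSF3 with at least 200 cDNAs per locus. Of the loci beyond 2-fold, that filter removed only lower ones, because the SRSF3 chromatin file is far the larger. That turn therefore follows from the filter and says nothing about binding. In SRSF7, chromatin against nucleoplasm turned to 56 and 40 with positions counted and to 139 and 139 without the mitochondrial genome and the 10 highest loci.

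Both proteins showed related differences between chromatin and cytoplasm at part of the loci. Over the 547 loci compared in both, the log2 ratios had a Pearson correlation of 0.31 and a Spearman correlation of 0.30, across loci, which are not independent replicates. Chromatin-higher loci common to both proteins numbered 63, where independent lists would give 38.6, and cytoplasm-higher ones 64, where independent lists would give 43.9. Another 44 loci lay beyond 2-fold in opposite directions, where independent lists would give 83.9. The Spearman correlation was 0.62 with positions of at least 3 cDNAs and 0.05 when positions were counted in place of cDNAs.

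**Figure D3:**
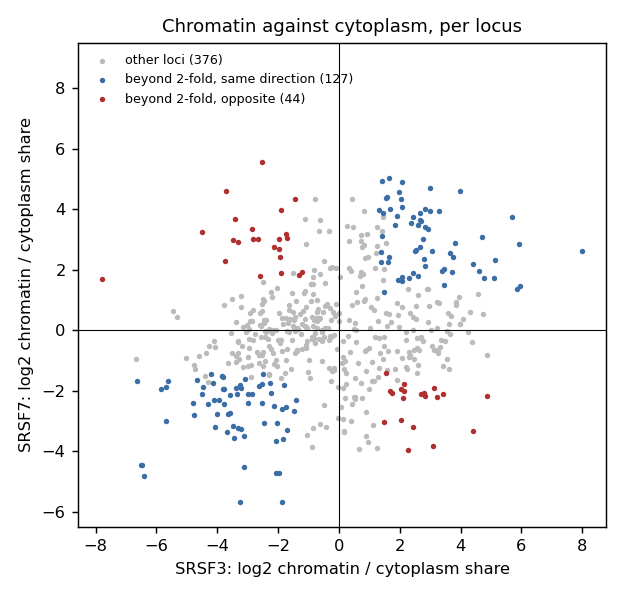
Log2 ratio of chromatin to cytoplasm share in SRSF3 (horizontal axis) and SRSF7 (vertical axis), 1 point per locus for 547 loci. Blue points (127) lie beyond 2-fold in the same direction in both proteins and red points (44) in opposite directions.

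The last comparison sets SRSF3 against SRSF7 within each fraction. SRSF7 positions lay within 5 nt of SRSF3 positions for 51.3% in chromatin (moved value 15.4%), 25.9% in nucleoplasm (5.85%) and 21.9% in cytoplasm (4.38%). In chromatin 291 of 1358 loci were beyond 2-fold higher in SRSF3 and 234 higher in SRSF7. In nucleoplasm the numbers were 139 and 200 of 1093, and in cytoplasm 121 and 179 of 866. Loci with at least 50 cDNAs in 1 protein and none listed in the other were not compared. Only in SRSF3 and only in SRSF7, they numbered 984 and 8 in chromatin, 19 and 47 in nucleoplasm, and 3 and 131 in cytoplasm. SRSF3-higher loci in chromatin were long, with a median span of 62.9 kb against 1.17 kb for SRSF7-higher ones. In nucleoplasm and cytoplasm the order was the other way, with 4.59 kb against 32.7 kb and 3.00 kb against 25.4 kb. Spans come from positions of all 6 files joined, of which SRSF3 chromatin lists the most.

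One region of chromosome 17 led the SRSF7-higher loci. The minus strand at 80586414 to 80606648 held 2.91%, 5.23% and 2.25% of SRSF7 cDNAs in chromatin, nucleoplasm and cytoplasm, and 0.0858%, 0.0532% and 0.00506% of SRSF3 cDNAs. The log2 ratio of SRSF3 to SRSF7 was -6.62 in nucleoplasm (-6.85 to -6.40) and -8.80 in cytoplasm (-9.71 to -8.02), the lowest in each among loci with at least 10 cDNAs in both files. The next locus on the same strand, at 80637679 to 80689490, had 78 cDNAs in SRSF3 chromatin and 1407 in SRSF7 chromatin, a log2 ratio of -7.00 (-7.35 to -6.67). In chromatin the lowest ratio was on the minus strand of chromosome 7 at 67331034 to 67365292, with 16 and 365 cDNAs and -7.34 (-8.17 to -6.62). Other SRSF7-higher loci were the plus strand of chromosome 12 at 110781914 to 110809746 in nucleoplasm, at -5.39 (-6.09 to -4.76), and the plus strand of chromosome 4 at 126698562 to 126716356 in cytoplasm, at -5.18 (-6.14 to -4.36).

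Among SRSF3-higher loci the minus strand of chromosome 17 at 29291288 to 29350503 came first in cytoplasm, with 211 cDNAs against 13 and a log2 ratio of 4.54 (3.73 to 5.47). It came next to the top in nucleoplasm at 3.83 (2.95 to 4.85). The top there was the minus strand of chromosome 1 at 155356568 to 155356826, with 209 cDNAs against 11, at 4.05 (3.18 to 5.07). The 5 nt on chromosome 7 at 111785248 to 111785252 had 415 cDNAs in SRSF3 cytoplasm and 27 in SRSF7 cytoplasm, at 4.46 (3.89 to 5.07). In chromatin the highest ratios were on the minus strand of chromosome 3 at 93137506 to 93215679, at 4.95 (4.32 to 5.66), and the minus strand of chromosome 1 at 170183140 to 170362332, at 4.66 (3.86 to 5.62).
The proteins were tagged in separate cell lines and differ in replicate number and depth, and possibly in peak calling, so these differences have no replicate check. In chromatin the split turned to 206 SRSF3-higher and 299 SRSF7-higher loci without the mitochondrial genome and the 10 highest loci, in nucleoplasm to 182 and 149, and in cytoplasm to 172 and 126.

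**Figure D4:**
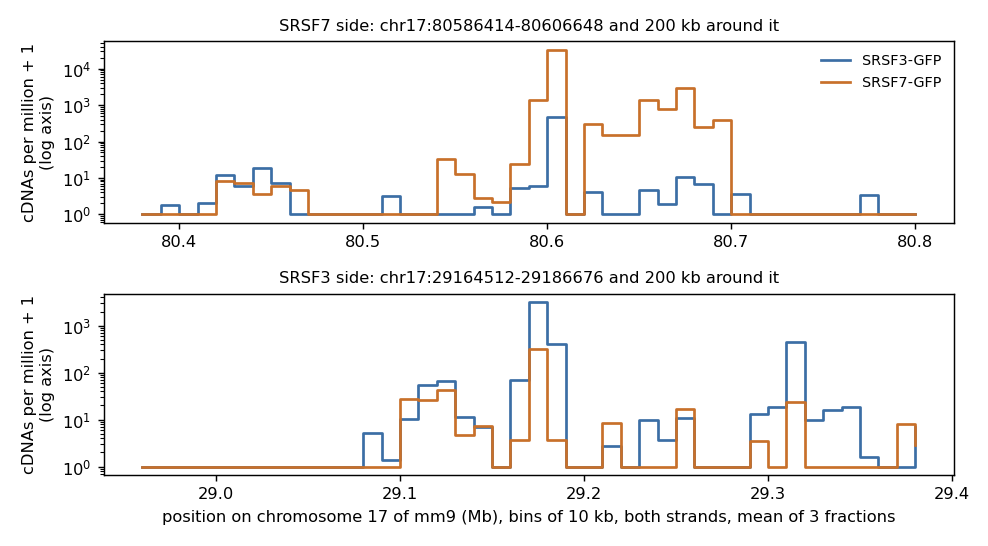
Listed cDNAs (vertical, log axis), scaled to the total of each file and offset by 1, in bins of 10 kb along chromosome 17 of mm9 (horizontal, Mb), both strands together, as the mean of the 3 fractions of each protein. The upper panel surrounds the locus at 80586414 to 80606648 and the lower panel the locus at 29164512 to 29186676, which was chosen after its values were seen.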

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

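The results here are loci whose contrast between fractions ran in opposite directions in the 2 proteins. The difference itself was not tested, since each protein and fraction is 1 pooled file and the intervals cover counting error only.

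Beyond 2-fold in opposite directions between chromatin and cytoplasm lay 44 of the 547 loci compared in both proteins. Independent lists would give 83.9, so such loci were fewer than expected without any relation between the proteins. Of the loci that the naming rule takes, 8 were among them. The plus strand of chromosome 11 at 68884516 to 68887316 held 0.456% of SRSF3 chromatin and 1.25% of SRSF3 cytoplasm, against 2.0% of SRSF7 chromatin and 0.0994% of SRSF7 cytoplasm. Its log2 ratio of chromatin to cytoplasm was -1.46 in SRSF3 (-1.52 to -1.40) and 4.33 in SRSF7 (4.18 to 4.49), a difference of 5.79. It rests on 8062, 3219, 4971 and 365 cDNAs, and it is the most deeply counted of the 8. On the minus strand of chromosome 19 at 4078318 to 4078514 the log2 ratios were -3.73 and 4.58, a difference of 8.31. On the minus strand of chromosome 12 at 103491728 to 103491897 they were -2.55 and 5.55, a difference of 8.10. On the minus strand of chromosome 7 at 111785248 to 111785252 they were -7.78 and 1.69, a difference of 9.47, with 13 cDNAs in SRSF3 chromatin and 27 in SRSF7 cytoplasm. On the plus strand of chromosome 1 at 46431078 to 46431111 they were -3.41 and 3.68, a difference of 7.08. The remaining 3 loci were long and ran the other way, higher in chromatin in SRSF3 and in cytoplasm in SRSF7. The minus strand of chromosome 1 at 54526595 to 54614497 had log2 ratios of 3.09 and -3.84, and SRSF7 minus SRSF3 gave -6.93. The plus strand of chromosome 3 at 129235325 to 129342573 had 4.88 and -2.18, giving -7.06. The plus strand of chromosome 14 at 48269019 to 48362074 had 2.69 and -2.12, giving -4.81.

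The locus with the highest share in every file also ran in opposite directions, here between chromatin and nucleoplasm. Its log2 ratio of nucleoplasm to chromatin was 0.83 in SRSF3 and -1.69 in SRSF7, so that SRSF7 minus SRSF3 gave -2.52. Because this locus held between 6.11% and 21.9% of a file, it lowers the share of all other loci where it is high.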

How the results depend on the processing

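The moved clusters, the 1000 nt joining, the mitochondrial alternatives and those of the correlation and the spans were chosen after seeing the data. No paired analysis was possible because each deposited list pools its replicates, and leaving out replicates in turn was not run for the same reason. Alternatives for region shares, introns, gene lists, site sequence and splice sites were not run, as no mm9 annotation was used here. Observed sharing exceeded the moved value in all 36 alternatives, by 2.34-fold or more. All used the same moving distance, with its limit for short loci. In the following lists the order within each protein is cytoplasm in chromatin, nucleoplasm in chromatin and cytoplasm in nucleoplasm, and then SRSF7 in SRSF3 for chromatin, nucleoplasm and cytoplasm. On the same nucleotide, sharing was 35.8%, 35.0% and 36.1% for SRSF3, 10.9%, 13.8% and 15.3% for SRSF7, and 36%, 14.6% and 12.5% between proteins. Within 30 nt it was 63.4%, 67.0% and 68.4%, then 26.4%, 35.9% and 44.4%, then 58.7%, 32.2% and 27.4%. Thinned files gave 39.2%, 39.7% and 58.5%, then 21.8%, 27.2% and 34.0%, then 39.3%, 25.6% and 23.8%. Positions of at least 3 cDNAs gave 64.3%, 70.1% and 72.9%, then 48.5%, 56.5% and 53.2%, then 77.5%, 52.2% and 53.6%.

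That filter left 103615, 17579 and 13247 SRSF3 positions and 14157, 14992 and 16856 SRSF7 positions in chromatin, nucleoplasm and cytoplasm. It left 848205 cDNAs in SRSF3 chromatin, 206337 in SRSF3 nucleoplasm, 137432 in SRSF7 nucleoplasm and 218066 in SRSF7 cytoplasm. Clusters in all 3 fractions then numbered 1321 for SRSF3 and 813 for SRSF7. For the unfiltered clusters, 3434 and 3151 as observed, a repeat of the moved draws gave 1482 and 1442. No moved value was computed with the filter. Loci beyond 2-fold with that filter numbered 284 and 342 in SRSF3 chromatin against cytoplasm and nucleoplasm. In SRSF7 they were 159 and 165 for the same pairs and 200 for nucleoplasm against cytoplasm, and between the proteins 183, 157 and 103. At least 200 cDNAs per locus, by its construction, tested fewer loci and gave 361, 452 and 109 in SRSF3 (chromatin against cytoplasm, chromatin against nucleoplasm, nucleoplasm against cytoplasm) and 185, 160 and 244 in SRSF7. Between the proteins it gave 152 in nucleoplasm and 151 in cytoplasm. Counting positions gave 367 in SRSF3 chromatin against cytoplasm and 48 in nucleoplasm against cytoplasm, 164, 96 and 241 in SRSF7, and 309, 163 and 146 between the proteins. Thinning gave 360 and 387 in SRSF3 chromatin against cytoplasm and nucleoplasm.

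Beyond the splits given with the results, counting positions moved the split to 50 higher and 317 lower in SRSF3 chromatin against cytoplasm, and leaving out the mitochondrial genome and the 10 highest loci moved it to 131 and 480. In SRSF3 chromatin against nucleoplasm, thinning gave 217 higher and 170 lower. In SRSF7 chromatin against nucleoplasm, counting positions gave 56 and 40, and leaving out the mitochondrial genome and the 10 highest loci 139 and 139. In SRSF7 nucleoplasm against cytoplasm, counting positions gave 100 and 141. In SRSF3 against SRSF7 chromatin, thinning gave 270 and 108, and counting positions 73 and 236. In cytoplasm, positions of at least 3 cDNAs gave 52 and 51. The ratio of the median spans of chromatin-higher to cytoplasm-higher loci was 9.64 in thinned SRSF3 files, 40.2 with at least 3 cDNAs and 30.55 with loci joined at 1000 nt, against 29.4 in the full files. In SRSF7 it reversed from 0.606 to 17.8 with at least 3 cDNAs and to 2.64 with loci joined at 1000 nt, and the cause was not tested. The Spearman correlation between the proteins was 0.62 with at least 3 cDNAs and 0.0514 with positions counted, and the cause was not tested. Of 31 alternative values of named loci, 25 stayed within their interval, 6 lay outside it and none turned sign. A value was counted only where both files kept cDNAs at the locus. With positions of at least 3 cDNAs, several named ratios had none left in 1 file and were left out. Among them were chromosome 8 at 49515773 in SRSF3, chromosome 10 at 56096419 in SRSF7, and chromosome 7 at 67331034 between the proteins in chromatin. Those ratios were therefore checked by thinning only. In cytoplasm, 1676 SRSF3 loci with at least 50 chromatin cDNAs were not listed, and whether depth is the reason was not tested.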

Other observations

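Of the tests below, those of the carry-over of cytoplasmic RNA and of the chromosome 17 neighbours were chosen after the result was seen, with their thresholds. Those of the tall mitochondrial positions and of the locus spans were chosen before.

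Mitochondrial cDNAs were spread unevenly along that genome, and no control was at hand to show that they mark binding. Plus-sign cDNAs lay mainly in its first 3000 nt. The kilobase from 1001 to 2000 held 47.5% of plus-sign mitochondrial cDNAs in SRSF3 nucleoplasm, 17.6% in SRSF3 cytoplasm, 26.2% in SRSF7 nucleoplasm and 20.8% in SRSF7 cytoplasm. Minus-sign mitochondrial cDNAs reached 1.72% of SRSF3 cytoplasm and 0.820% of SRSF7 cytoplasm, and stayed at 0.0983% and 0.0964% in nucleoplasm. In SRSF3 cytoplasm, the kilobase from 5001 to 6000 held 53.3% of them.

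Long loci, of 100 kb or more, held 15.1% of SRSF3 chromatin cDNAs, 1.31% in nucleoplasm and 0.378% in cytoplasm. In SRSF7 they held 3.51%, 2.87% and 1.63%. Loci under 1 kb ran the other way in SRSF3, from 8.36% in chromatin through 23.6% in nucleoplasm to 30.1% in cytoplasm, while in SRSF7 they held 22.4%, 14.7% and 23.0%. Loci were joined over all 6 files and SRSF3 chromatin lists 870234 of the positions, and its share in long loci was not corrected for this.

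The mitochondrial share was 6.79-fold higher in SRSF3 than in SRSF7 nucleoplasm. A few tall positions were argued against, because without the 10 tallest mitochondrial positions of each file the ratio was 8.66. Carry-over of all cytoplasmic RNA at 1 weight was argued against by the minus-sign mitochondrial cDNAs, whose share in SRSF3 nucleoplasm was 0.0572 times that in cytoplasm (0.0508 to 0.0642), against 0.647 for plus-sign ones. The nuclear-genome loci higher in SRSF3 cytoplasm than in chromatin did not exclude it, since their median nucleoplasm to cytoplasm ratio was 0.688 (quartiles 0.370 and 1.11). Carry-over of some RNAs only, a fractionation that differed between the cell lines, and a difference between the proteins stay open, and none of these was tested. Whether these cDNAs are background was not tested either, for want of a control.

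Chromatin-higher loci were 29.4 times as long as cytoplasm-higher ones in SRSF3, by median span. Greater depth of the SRSF3 chromatin file may let weakly bound long loci pass the threshold, and in SRSF7, where the chromatin file is the smaller, the ratio was 0.606. That value fell on the side that depth predicts, but it was 17.8 with positions of at least 3 cDNAs and 2.64 with loci joined at 1000 nt. In SRSF3 the ratio was 9.64 after thinning, which does not undo the authors' threshold, but 40.2 and 30.55 in those 2 settings. Against nucleoplasm, loci higher in chromatin had the longer median span in SRSF3, at 54.3 kb against 3.58 kb, and the shorter in SRSF7, at 2.41 kb against 25.4 kb. Depth therefore cannot be told apart from a difference between the fractions, because the SRSF7 test changes side with the setting. Binding to long unspliced RNA on chromatin stays open and was not tested, as introns were not annotated here.

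Loci on both strands around the SRSF7-higher locus of chromosome 17 were also higher in SRSF7. Of the 6 other loci with at least 15 cDNAs within 150 kb, 5 lay higher in SRSF7. Higher here means any difference in mean share over the 3 fractions. Of 86 windows with at least 5 such loci around other loci of at least 1000 cDNAs, 1 did as much. On the SRSF3 side 25 of 87 windows met the corresponding condition, so how rare it is differs by side. A single RNA at that locus was argued against, because 4 loci over 10 kb away lay beyond 2-fold higher in SRSF7. Among these, the plus strand at 80621292 to 80637074 had 280 SRSF7 cDNAs and none listed in SRSF3, and at 80689635 to 80694924 it had 330 and none. A candidate explanation is extra copies of the SRSF7-side region in the SRSF7 cell line, such as a tagged transgene with its surroundings would bring; the thresholds were set with these values in view, so 5 of 6 cannot count as independent evidence.

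The SRSF3-side locus, on the plus strand at 29164512 to 29186676, had 6261 cDNAs in SRSF3 chromatin and 75 in SRSF7 chromatin. Extra copies of the SRSF3-side region in the SRSF3 cell line cannot be told apart from other differences. Of 7 loci within 150 kb, 4 lay higher in SRSF3 by mean share. The full condition (at least 5 loci and over 75% higher) was met by 25 of 87 other windows. The loci not higher were thinly counted, with 46, 9 and 10 SRSF3 cDNAs against 11, 7 and 13 SRSF7 ones. Those higher held 621, 366, 17 and 756 against 73, 3, 0 and 24. The count of 4 therefore says little, and the verdict rests on the other windows. A scan of 3556 bins of 100 kb with at least 100 cDNAs found 23 bins whose interval lay beyond 2-fold higher in SRSF7 in each of the 3 fractions and 18 beyond 2-fold higher in SRSF3. This scan was chosen after seeing the data, in place of one with 0.5 added to each count, which had called 2 bins with 0 cDNAs of both proteins in chromatin. The bins at 80500001 to 80600000 and 80600001 to 80700000 were among those higher in SRSF7, and those at 29300001 to 29400000 and 29100001 to 29200000 among those higher in SRSF3. Other bins met the same condition. By the weakest of the 3 bounds on log2 SRSF7 to SRSF3, the bins at 80500001 and 80600001 led, at 5.22 and 5.20. Next on the SRSF7 side was 3.10, on chromosome 13. On the SRSF3 side those at 29100001 and 29300001 led, at -2.75 and -2.59, before -1.77 on chromosome 6. This order was taken after seeing the data and depends on counts. In the replaced scan these bins ranked 2, 3, 10 and 6 on their own sides. Whether any bin holds a tagged gene was not analysed here.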
